A study of Mus musculus with 17 samples.

How the data were processed

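RNA from NIH 3T3 cells, a mouse embryonic fibroblast line, was measured on 17 oligonucleotide arrays of 2 designs, in which a set of short probes reports on a transcript. Per the labels, the cells were quiescent, and the treatments were PDGF at 25 ng/ml, SU6656 at 2 µM, UO126 at 10 µM, PD98059 at 7.5 µM and LY294002 at 7.5 µM. The labels describe 3 experiments with 1 array per condition. The Src experiment fills a table of 8 arrays (vehicle, SU6656, UO126 and LY294002, each without and with PDGF for 1 h). A table of 9 arrays holds the MEK experiment (untreated, UO126, PD98059, PDGF, PDGF with UO126, PDGF with PD98059; PDGF time not given in the sources used here) and a repeat of the Src experiment (vehicle, PDGF, and PDGF with SU6656, 1 h of PDGF). The labels call the control of the MEK experiment untreated and those of the other experiments vehicle-treated. Nothing in the labels says that arrays came from separate cultures. P-values therefore measure only the spread between these arrays, which can be technical and includes treatment differences without a term in the fit.

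The deposited values are intensity on a linear scale, 1 positive number per probe set and array. The mean of each array after trimming 2% of probe sets at each end was 500.2 to 500.4, so the deposited intensity of every array had been scaled to a common trimmed mean. The software that made these values, and any genome build, are not given in the sources used here. Medians per array were 174.7 to 198.4 signal units in the 8-array table and 133.7 to 156.1 in the 9-array table. Spearman's rho between arrays was 0.945 to 0.962 in the 8-array table and 0.932 to 0.967 in the 9-array table. In the latter its median was 0.961 within an experiment and 0.94 between experiments, so every ratio was taken within 1 experiment or with the experiment in the fit. The number of arrays limits the precision of every comparison.

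The 8-array table has 22690 probe sets, 64 of them controls, and the 9-array table has 12488, 66 of them controls. Gene names came from the platform annotation, with 20364 and 10839 symbols updated through their Entrez IDs against a RefSeq gene table of assembly GRCm38.p6, used for names alone. Of the probe sets in the 8-array table, 20393 had 1 gene, 691 had several and 1606 were unlisted. In the 9-array table the numbers were 10855, 396 and 1237. Genes were named from probe sets with 1 gene only.

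Values were quantile normalised within each table after control probe sets were left out. They were transformed as log2 of the value plus the table's 20th percentile (36.3 and 21.2 signal units), so fold changes of dim probe sets are understated. The lowest 30% of probe sets by mean were left out, which kept 15838 and 8695 probe sets and 9221 and 6364 genes. Results per gene (lists, responses over basal and inhibitor changes) used the probe set with the highest mean. The largest changes named from a fit are per probe set, each gene at its probe set with the largest change past the threshold, or the smallest p where none passed, and the value of its brightest probe set is given where it differs. The 2 tables, normalised separately, were never tested together, and levels were never compared between them.

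Models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend), with Benjamini-Hochberg adjustment over all probe sets kept and a threshold of 0.05. The PDGF effect was fitted in each table over 4 pairs of arrays without and with PDGF, with the pair as a block. The pairs come from the design, since both arrays of a pair share experiment and inhibitor. In the 8-array table the same additive fit gave the effects of SU6656, UO126 and LY294002, each 2 arrays against the same 2 vehicle arrays. In the 9-array table UO126 and PD98059 served as 2 replicates of MEK inhibition, with PDGF, experiment, SU6656 and the interaction of PDGF with MEK inhibition as terms. A fit with a separate term per MEK inhibitor compared UO126 with PD98059. Residual degrees of freedom were 3, or 2 in the latter fit. This residual is not a spread of replicates. In the PDGF fits and the 8-array inhibitor fits it holds any difference in PDGF effect between pairs, and so any interaction with an inhibitor. In the 9-array inhibitor fits it holds differences between UO126 and PD98059 that have no term, and those in PDGF effect between experiments.

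Untested summaries were also computed. Genes at least 2-fold up or down with PDGF over basal in all 3 experiments were counted beside the number expected of independent lists. For each inhibitor, the median change under PDGF was taken over genes induced at least 2-fold in every experiment of the other table, so that no array both chose and measured a gene. This median was set against 10000 random lists matched on mean expression in 20 bins, with intervals from 2000 bootstrap draws over genes. Inhibitor changes of genes up in all 3 experiments were correlated across genes between arrays of the 2 tables. Intervals over genes describe these arrays, since genes are not independent replicates.

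The lists were immediate early transcription factors, MAPK feedback regulators, SRF and MRTF cytoskeletal targets, inflammatory NF-κB targets, AU-rich mRNA decay factors, secreted growth factors and cytokines, matrix and protease genes, FOXO targets, SREBP sterol genes, growth arrest and quiescence genes, cell cycle genes of S to M phase, ribosome biogenesis genes, the aryl hydrocarbon receptor battery, p53 targets, heat shock and unfolded protein response genes, interferon response genes and housekeeping genes. Marker lists covered fibroblasts, epithelium, macrophages and leukocytes, endothelium, and adipocytes with muscle. Each was tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over lists. The latter is estimated from the residual of each fit, with 3 or 2 degrees of freedom, so few lists can pass with it. Groups, designs, lists, the rule for named genes and most alternatives were fixed before the data were examined. Camera on the inhibitor fits, the leaving out of whole experiments and 2 checks of gene subsets were added later.

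Named genes were the 20 with the largest smallest-of-3 PDGF response and those down in all 3 experiments (5 at most), the 5 lowest and 3 highest genes per inhibitor among genes up in all 3 experiments, up to 4 members per list with the largest mean PDGF effect, and the 5 largest changes past the threshold in each fit. A gene outside this rule is said to be so where it appears.

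All fits except the UO126 and LY294002 effects in the 8-array table were tested on simulated data with 200 changed probe sets. The PDGF fits recovered 83% and 84% of 2-fold changes (8-array and 9-array table), the MEK inhibition fit 58%, the interaction 26%, the comparison of UO126 with PD98059 65% and the SU6656 fit 73%. For 4-fold changes the shares were 99%, 100%, 92%, 86%, 93% and 95%. False calls numbered 14, 6, 10, 13, 8 and 7, of 196, 190, 160, 125, 166 and 175 called. The simulated noise was normal and independent between arrays. It lacked the differences between pairs and inhibitors that the real residual holds, so these numbers may not carry over to the arrays. Alternatives covered scaling (values as deposited, or scaled to a common median), the offset, the filter, the trend, the block, the fold threshold, the choice of probe sets, and each array left out in turn. Every deposited array entered the main results. The array of PDGF with SU6656 in the repeat has no partner and was left out of the PDGF fit of the 9-array table. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.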

Results

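The series measured how PDGF, a fibroblast mitogen, changed transcript levels in quiescent NIH 3T3 cells, and how inhibitors of signalling kinases altered that response. NIH 3T3 is a mouse embryonic fibroblast line. SU6656 inhibits Src family kinases, UO126 and PD98059 inhibit MEK, the kinase that activates ERK, and LY294002 inhibits PI3K. The 17 arrays form 3 experiments: a MEK experiment of 6 arrays, a Src experiment of 8 arrays and a repeat of the latter with 3 arrays. The first and the last are of 1 array design and make up the 9-array table, and the Src experiment is the 8-array table. Each condition was measured on 1 array per experiment, so values of a single condition have no replicate within an experiment. Array medians lay between 133.7 and 198.4 signal units. No genome build is given in the sources used here, so genes are given by symbol without coordinates.

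PDGF over basal was the comparison made in all 3 experiments. Errfi1, which encodes an inhibitor of EGF receptor signalling, had a log2 response of 4.68 ± 0.31 (SD, n = 3 experiments), a 25.6-fold mean. Dusp6, a phosphatase of ERK, had 4.43 ± 0.51, Egr2, a zinc finger transcription factor, 4.05 ± 0.38, and Ptgs2, the inducible cyclooxygenase, 3.86 ± 0.18. In the Src experiment the signal of Dusp6 was 63.5 on the vehicle array and 1397.1 on the PDGF array. Ccl2, a monocyte chemokine, was the most variable of the named genes at 4.26 ± 1.58, with 3.15 in the MEK experiment, 3.56 in the Src experiment and 6.07 in its repeat. The other genes named by the size of their smallest response were Ereg, Btg2, Fosl1, Egr1, Nr4a1, Phlda1, Atf3, Ccl7, Fosb, Junb, Ccn1, Sgk1, Ier3, Bhlhe40 and Socs1, all at least 4.08-fold up in each experiment. Of 5530 genes measured in both tables, 54 were at least 2-fold up in all 3 experiments, against 0.112 expected of independent lists of 166, 117 and 177 genes.

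**Figure D1:**
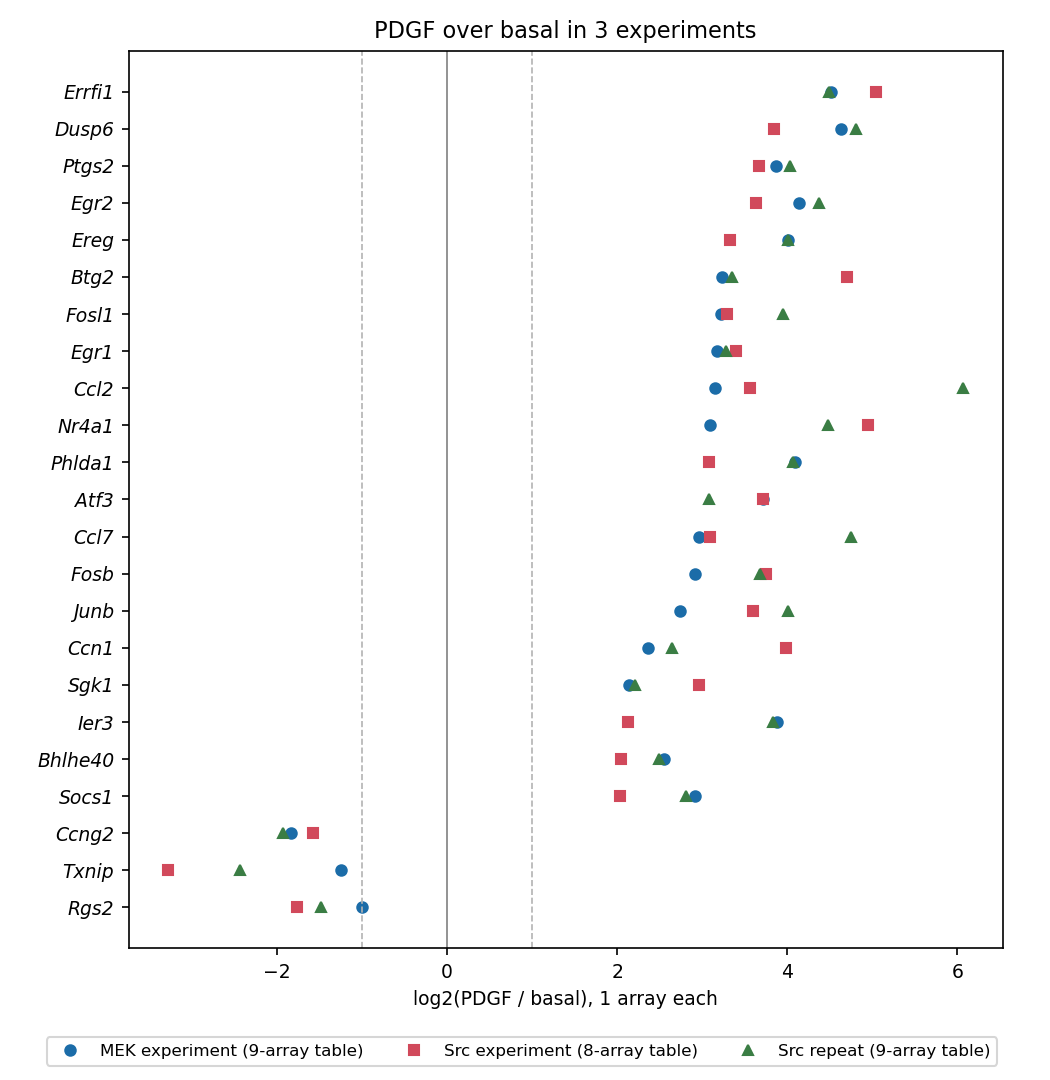
PDGF over basal on a log2 scale for the 20 genes with the largest smallest-of-3 response and the 3 genes at least 2-fold down in all 3 experiments, 1 point per experiment and no error bars, with dashed lines at 2-fold. Errfi1 lies between 4.49 and 5.04, and Ccl2 has the widest range of the 20 upper genes, 3.15 to 6.07.

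Fewer genes were down. Ccng2, an unconventional cyclin linked to growth arrest, had a log2 value of −1.78 ± 0.18 (SD, n = 3), Txnip, the thioredoxin inhibitor, −2.32 ± 1.02, and Rgs2, a regulator of G protein signalling, −1.42 ± 0.39. These were the only genes at least 2-fold down in all 3 experiments, against 0.0259 expected of lists of 117, 41 and 165. The number was 8 without the MEK experiment, 17 without the Src experiment and 4 without the repeat. For Txnip the 9-array table has probe sets that differed, with PDGF effects of −1.32 and 0.20, and the call for the former was lost without the untreated or the PDGF array of the MEK experiment (log2 −1.35). When probe sets that can match several transcripts were left out, its smallest response was 0.63.

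Over 4 pairs per table, 396 probe sets rose and 129 fell with PDGF in the 8-array table, from 265 and 103 named genes, with 35 called probe sets unnamed. For the 9-array table the numbers were 124 and 23, from 107 and 20 named genes, with 8 unnamed. The largest rises in the 8-array table were those of Nr4a1, an orphan nuclear receptor (log2 4.83, SE 0.155, adjusted p = 2.83e-07), Errfi1 (4.57, SE 0.147), Btg2, an antiproliferative factor (4.45, SE 0.103), the matricellular gene Ccn1 (4.18, SE 0.36) and Egr2 (3.94, SE 0.201). Those in the 9-array table were of Egr2 (4.06, SE 0.151, adjusted p = 4.4e-07), Dusp6 (4.03, SE 0.258), Errfi1 (3.86, SE 0.235), Nr4a1 (3.83, SE 0.181) and the AP-1 component Junb (3.78, SE 0.297; 2.85 at its brightest probe set). Among genes in both tables, 186 rose in the first and 101 in the second, 82 in both, against 3.4 expected of independent lists. For falls the numbers were 54, 14 and 7, against 0.137. The fits used pairs as a block; without it 244 and 60 probe sets passed. In the 8-array table the count of 525 was 262 without the PDGF array, 265 without the vehicle array, 335 without PDGF with LY294002, 340 without LY294002, 341 without SU6656 and 345 without PDGF with SU6656, and without the variance trend the counts were 184 and 65. With scaling to a common median the split in the 8-array table was 578 up and 65 down. Falls were less stable than the totals. Without any 1 array, 37 to 76 probe sets fell in place of 129, and 7 to 13 in place of 23 in the 9-array table. Without the filter 66 and 9 fell. The untreated array of the MEK experiment had a Gapdh 3′ to 5′ signal ratio of 1.13, against 0.739 to 0.907 on all other arrays. Its actin ratio, 1.47, was below the 1.67 of the vehicle array of the repeat. Without the untreated array 101 probe sets passed in the 9-array table, against 147 with it. That loss was not particular to it, since leaving out any 1 array of the fit gave 98 to 111.

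Immediate early transcription factors formed the group that moved most. Of 30 measured members in the 8-array table, 23 rose and 0 fell (26 up adjusted over the list alone), with a median log2 of 1.26. Camera gave an adjusted p = 4.03e-47 (adjusted p = 0.0317 with an estimated correlation). Of the 27 members in the 9-array table, 19 rose (24 adjusted over the list alone) with a median of 1.59 and an adjusted p = 1.15e-47 (adjusted p = 0.0104 with an estimated correlation). Egr1, an early growth response factor, rose by 3.31 (SE 0.288) and 3.25 (SE 0.113) in the respective tables. This was the only list whose camera call held with an estimated correlation in any fit. With so few residual degrees of freedom, a call lost in this way does not show that a list did not move.

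Among MAPK feedback regulators, 8 of 18 rose and 1 fell in the 8-array table (11 and 2 adjusted over the list alone; camera adjusted p = 2.91e-11, and adjusted p = 0.0747 with an estimated correlation), and 6 of 13 rose and 1 fell in the 9-array table (7 and 1 adjusted over the list alone; adjusted p = 1.07e-09, and adjusted p = 0.0817 with an estimated correlation). Phlda1 rose by 2.71 (SE 0.157) and 3.47 (SE 0.231), and Spry2, a Sprouty inhibitor of receptor tyrosine kinase signalling, by 2.53 (SE 0.175) in the 8-array table. The member that fell in both was Rgs2. Inflammatory NF-κB targets rose in 6 of 16 cases in the 8-array table (6 up and 1 down adjusted over the list alone; adjusted p = 1.15e-05, and adjusted p = 0.212 with an estimated correlation) and in 8 of 17 in the 9-array table (8 and 0 adjusted over the list alone; adjusted p = 4e-14, and adjusted p = 0.0817 with an estimated correlation). They included Ptgs2 (3.48, SE 0.099, and 3.44, SE 0.198), the chemokines Ccl7 (3.24, SE 0.308, and 3.46, SE 0.265) and Ccl2 (2.79, SE 0.343, and 3.73, SE 0.438), and Cxcl1 (1.69, SE 0.19, 9-array table).

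Secreted growth factors and cytokines rose in 3 of 14 cases with 1 fall in the 8-array table (4 and 1 adjusted over the list alone; camera adjusted p = 0.000202, and adjusted p = 0.108 with an estimated correlation). Rises in the 9-array table numbered 4 of 12 (6 adjusted over the list alone; adjusted p = 4.55e-06, and adjusted p = 0.104 with an estimated correlation). Ereg, an EGF family ligand, rose by 3.25 (SE 0.189) and 2.81 (SE 0.418), and the latter call was lost without the vehicle or the PDGF array of the repeat (2.42). Hbegf, another ligand of the EGF receptor, rose by 2.79 (SE 0.202) in the 8-array table, and Inhba and Vegfa by 1.70 (SE 0.195) and 1.42 (SE 0.161) in the 9-array table; in the 8-array table these had 0.99 (SE 0.369) and 0.35 (SE 0.106), neither past the threshold. Matrix and protease genes rose in 5 of 13 cases (6 adjusted over the list alone; adjusted p = 2.71e-08, and adjusted p = 0.0747 with an estimated correlation) and in 2 of 10 (5 adjusted over the list alone; adjusted p = 4.55e-06, and adjusted p = 0.206 with an estimated correlation). Tissue factor, F3, rose by 1.93 (SE 0.146) and 1.49 (SE 0.195), Plaur, the urokinase receptor, by 1.11 (SE 0.149) and 1.37 (SE 0.191), and Thbs1, thrombospondin, by 1.90 (SE 0.094) in the 8-array table.

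For SRF and MRTF cytoskeletal targets 10 of 23 rose in the 8-array table (11 adjusted over the list alone; camera adjusted p = 3.35e-16, and adjusted p = 0.0747 with an estimated correlation), among them Ccn2 (3.13, SE 0.281) and Srf itself (0.84, SE 0.121). Of 21 members in the 9-array table, 2 rose, Ccn1 (2.55, SE 0.172) and Ccn2 (1.84, SE 0.112), also 2 when adjusted over the list alone. There the list's median was −0.02, of other sign than its mean of 0.17 and camera's direction, up, and camera gave an adjusted p = 0.124. AU-rich mRNA decay factors rose in 3 of 13 cases (6 up and 1 down adjusted over the list alone; adjusted p = 0.000165, and adjusted p = 0.0747 with an estimated correlation) and in 3 of 11 (4 adjusted over the list alone; adjusted p = 6.96e-05, and adjusted p = 0.104 with an estimated correlation). Zfp36l1 rose by 1.53 (SE 0.117) and 1.73 (SE 0.1), and Zfp36l2 by 1.13 (SE 0.113) and 1.09 (SE 0.079). These encode proteins that bind AU-rich elements and promote mRNA decay.

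Of 19 FOXO targets in the 8-array table, 5 fell and 1 rose, also 5 and 1 when adjusted over the list alone. The list had a median of −0.31 (camera's direction down, adjusted p = 4.78e-05, and adjusted p = 0.0747 with an estimated correlation). Txnip fell by 2.51 (SE 0.201), Ccng2 by 1.62 (SE 0.155) and Ddit4, an inhibitor of mTORC1 signalling, by 1.24 (SE 0.116), while the transcriptional co-regulator Cited2 rose by 1.14 (SE 0.079). Of 18 members in the 9-array table, 4 fell, 1 rose and 13 did not pass (6 down and 1 up adjusted over the list alone). There the median was −0.095 (camera's direction down, adjusted p = 0.0367, and adjusted p = 0.198 with an estimated correlation), and Ccng2 fell by 1.76 (SE 0.147). SREBP sterol genes rose in 8 of 16 cases in the 8-array table, also 8 when adjusted over the list alone (adjusted p = 2.12e-10, and adjusted p = 0.0747 with an estimated correlation). They included Hmgcs1 (0.97, SE 0.109), Stard4 (0.86, SE 0.092) and Msmo1 (0.66, SE 0.074), genes of cholesterol synthesis and transport. Of 14 members in the 9-array table, 1 rose (2 adjusted over the list alone; adjusted p = 0.0316, and adjusted p = 0.198 with an estimated correlation), and Hmgcs1 had 0.12 (SE 0.088), not past the threshold.

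Heat shock and unfolded protein response genes rose in 4 of 17 cases with 1 fall (11 and 2 adjusted over the list alone; camera adjusted p = 2.71e-08, and adjusted p = 0.0747 with an estimated correlation) and in 3 of 16 (6 up and 1 down adjusted over the list alone; adjusted p = 0.000463, and adjusted p = 0.104 with an estimated correlation). Dnajb1, a cochaperone, rose by 1.89 (SE 0.229) in the 8-array table, and Ddit3, a stress-induced transcription factor, by 1.01 (SE 0.116) in the 9-array table. In the 8-array table Ddit3 had 0.50 (SE 0.127, limma adjusted p = 0.0766), not past the threshold. Of p53 targets, 3 of 11 rose and 1 fell (4 and 2 adjusted over the list alone; adjusted p = 0.00258, and adjusted p = 0.294 with an estimated correlation), and 2 of 8 rose in the 9-array table (3 adjusted over the list alone; adjusted p = 0.00266, and adjusted p = 0.132 with an estimated correlation). The members that rose in both were Btg2, which is also in the list of immediate early factors, and Plk2 (0.75, SE 0.064, and 0.65, SE 0.079). In the aryl hydrocarbon receptor battery 1 of 5 rose in each table, Tiparp (1.26, SE 0.144, and 2.28, SE 0.29), with 1 up and 1 down adjusted over the list alone in each. Its medians of −0.01 and −0.19 differed in sign from its means of 0.15 and 0.28; camera's direction was up (adjusted p = 0.705) and down (0.914).

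Several lists held 0 members past limma's threshold over all genes in both tables. For cell cycle genes the medians were −0.11 over 18 and −0.14 over 20 members, with camera's adjusted p = 0.405 and 0.0474, the latter with adjusted p = 0.199 with an estimated correlation. Ribosome biogenesis genes had medians of 0.01 and 0.05 over 19 and 18 members (adjusted p = 0.162 and 0.626), interferon response genes 0.07 and −0.08 over 10 and 9 (0.634 and 0.954), and housekeeping genes −0.00 and −0.09 over 10 each (0.784 and 0.626; the former mean was 0.02 and camera's direction up). Adjusted over the list alone, these 4 lists had 0 members past the threshold except 1 housekeeping gene up in the 8-array table. Growth arrest and quiescence genes had 0 of 15 in the 8-array table (1 up adjusted over the list alone) and 1 of 15 in the 9-array table (1 up and 2 down adjusted over the list alone), with camera's adjusted p = 0.385 and 0.824, and in the latter a median of 0.01, a mean of −0.07 and camera's direction down. There Pdgfra, a PDGF receptor, fell by 0.65 (SE 0.116), a call lost without any 1 of the 8 arrays (−0.70 to −0.61).

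Markers of the fibroblast and of other cell types gave few calls. Fibroblast markers had 0 of 13 past the threshold in each table, with medians of −0.04 and −0.04 (camera adjusted p = 0.655 and 0.257; adjusted over the list alone, 0 and 1 down). Macrophage and leukocyte markers had 0 of 6 and 0 of 5 (0.431 and 0.626), and adipocyte and muscle markers 0 of 5 and 0 of 6 (0.705 and 0.914), both with 0 adjusted over the list alone. Among epithelial markers 1 of 5 and 0 of 4 passed, also when adjusted over the list alone (0.475 and 0.914): Cldn3, a claudin, rose by 1.42 (SE 0.272) in the 8-array table, a call lost without either array of the vehicle, LY294002 or UO126 pair (1.20 to 1.41). Among endothelial markers 1 of 4 and 0 of 3 passed, also when adjusted over the list alone (0.385 and 0.954; the latter with a median of −0.24 and camera's direction up): Eng, endoglin, fell by 1.29 (SE 0.24) in the 8-array table, a call lost without either array of the vehicle, SU6656 or UO126 pair (−1.21 to −1.14).

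The MEK experiment asked which PDGF-induced genes depend on MEK. Under PDGF, the genes with the lowest values in the weakest of their 3 contrasts (UO126 in both experiments and PD98059) were Errfi1 (−1.75, −1.21 and −1.41 for UO126 and PD98059 in the MEK experiment and UO126 in the Src experiment), Dusp6 (−1.76, −1.66 and −1.16), the EGF receptor ligand Hbegf (−1.06, −1.48 and −1.24), the AP-1 component Fosl1 (−1.07, −1.04 and −1.17) and the kinase gene Sgk1 (−1.15, −0.98 and −1.14). The signal of Dusp6 in the MEK experiment was 73.7 untreated, 2348.9 with PDGF, 675.1 with PDGF and UO126, and 725.5 with PDGF and PD98059. Ranked instead by the smallest of the 3 values, the highest were Ccn2 (0.80, 0.32 and 0.34), Nfil3 (0.75, 0.24 and 0.25) and Adm, which encodes adrenomedullin (0.64, 0.80 and 0.22). The named genes were chosen by their response on the same PDGF arrays, which favours lower values with an inhibitor.

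With the 2 MEK inhibitors as replicates, limma called 0 probe sets under PDGF, while 625 of 8695 had an unadjusted p under 0.05. Dusp6 (−1.76, SE 0.218), Sgk1 (−1.08, SE 0.151) and Snai2, a zinc finger repressor (1.38, SE 0.191), had an adjusted p = 0.0606. The gene Ctrl had the same adjusted p (2.33, SE 0.301, at its probe set with the smallest p). Errfi1 (−1.47, SE 0.213) had an adjusted p = 0.0679. MAPK feedback regulators had a median of −0.38 (camera adjusted p = 5.53e-05, and adjusted p = 0.219 with an estimated correlation), with 0 of 13 called and 4 down adjusted over the list alone. Immediate early transcription factors had a median of −0.36 (adjusted p = 0.000563, and adjusted p = 0.219 with an estimated correlation), with 0 of 27 called, and 4 down and 1 up adjusted over the list alone. Secreted factors had a median of −0.20 (adjusted p = 0.011, and adjusted p = 0.324 with an estimated correlation), with 0 of 12 called and 2 down adjusted over the list alone. The count of 0 became 6 with the lowest 50% of probe sets left out, 3 with median scaling, 1 with values as deposited, 1 with a higher offset and 2 without the array of PDGF with PD98059.

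The interaction asked whether the PDGF response itself differed with MEK inhibited. Limma called 0 probe sets. Of 8695 tested, 427 had an unadjusted p under 0.05, a share no larger than the 0.05 expected with no effect. The smallest p-values belonged to Klf2, a Krüppel-like transcription factor (2.87, SE 0.409, adjusted p = 0.174), Ereg (−2.39, SE 0.348, adjusted p = 0.174) and Nr4a2, an orphan nuclear receptor (−2.20, SE 0.345, adjusted p = 0.216; −1.78 at its brightest probe set). Ctrl, Snai2, Klf2 and Nr4a2 were chosen after their values were seen. Camera passed matrix and protease genes (median −0.29, adjusted p = 0.000539, and adjusted p = 0.507 with an estimated correlation), secreted factors (median −0.47, adjusted p = 0.00119, and adjusted p = 0.379 with an estimated correlation) and MAPK feedback regulators (median −0.14, adjusted p = 0.00152, and adjusted p = 0.379 with an estimated correlation). These lists had 0 called members each, and 0, 2 and 4 down adjusted over the list alone. The count was 1 without the untreated array, the PDGF array, or the array of PDGF with PD98059 of the MEK experiment.

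UO126 and PD98059 are structurally distinct MEK inhibitors and were used at different doses, 10 and 7.5 µM. Over 117 PDGF-induced genes chosen in the other table, the median change was −0.26 with UO126 (−0.336 to −0.112, 95% bootstrap interval over genes) and −0.21 with PD98059 (−0.31 to −0.08), with 13 and 10 genes at least 2-fold lower and 5 and 3 at least 2-fold higher. Both medians lay below all 10000 random lists. Their median difference was −0.09 (−0.154 to −0.002), with 69 of 117 genes lower with UO126. The order of the 2 medians was not stable, with −0.14 for UO126 and −0.16 for PD98059 under median scaling, −0.25 and −0.26 with the offset at the 50th percentile, and −0.09 for both at a 1.5-fold threshold. Limma called 0 probe sets between them. Of 8695 tested, 456 had an unadjusted p under 0.05, a share close to the 0.05 expected with no difference. Dusp1, a MAPK phosphatase, had a difference of 1.09 (SE 0.179), Ptgs2 of 1.03 (SE 0.175) and Degs2, a sphingolipid desaturase, of 1.85 (SE 0.298), each with an adjusted p = 0.485. Dusp1 and Degs2 were chosen after their values were seen. Camera passed MAPK feedback regulators (median 0.17) and matrix and protease genes (median 0.17), both with an adjusted p = 0.0258 and an adjusted p = 0.781 with an estimated correlation, with 0 called members and 1 up and 0 adjusted over the list alone.

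In the Src experiment, UO126 against vehicle over both PDGF states gave 3 probe sets up and 4 down. Emp1, an epithelial membrane protein gene, fell by 1.22 (SE 0.126, adjusted p = 0.027) and Arf2, an ADP-ribosylation factor gene, by 1.69 (SE 0.187, adjusted p = 0.0332; −1.48 at its brightest probe set, also past the threshold). Prkrip1 rose by 1.98 (SE 0.247), the linker histone gene H1f2 by 0.67 (SE 0.078) and the nuclear noncoding RNA Neat1 by 0.52 (SE 0.065), each with an adjusted p = 0.0374. Prkrip1 also had 1.69 with LY294002 (adjusted p = 0.0216) and 1.66 with SU6656 (adjusted p = 0.0624), all against the same 2 vehicle arrays. SRF and MRTF targets had a median of −0.13 (camera adjusted p = 0.000585, and adjusted p = 0.726 with an estimated correlation), with 0 of 23 called and 1 down adjusted over the list alone. Over 73 PDGF-induced genes the median change under PDGF was −0.22 (−0.311 to −0.082), below all random lists, with 8 genes at least 2-fold lower and 1 higher. The 7 calls became 0 without the vehicle array, the PDGF array, the filter or the variance trend, and 2 without the UO126 array. All 3 rises, those of Prkrip1, H1f2 and Neat1, were also lost without the LY294002 array or PDGF with LY294002 (0 up and 5 down each) or PDGF with UO126 (0 up and 8 down). The call for Neat1 (0.52) was lost without any 1 of the 8 arrays, and that for Arf2 also without PDGF with UO126 (−1.77).

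**Figure D2:**
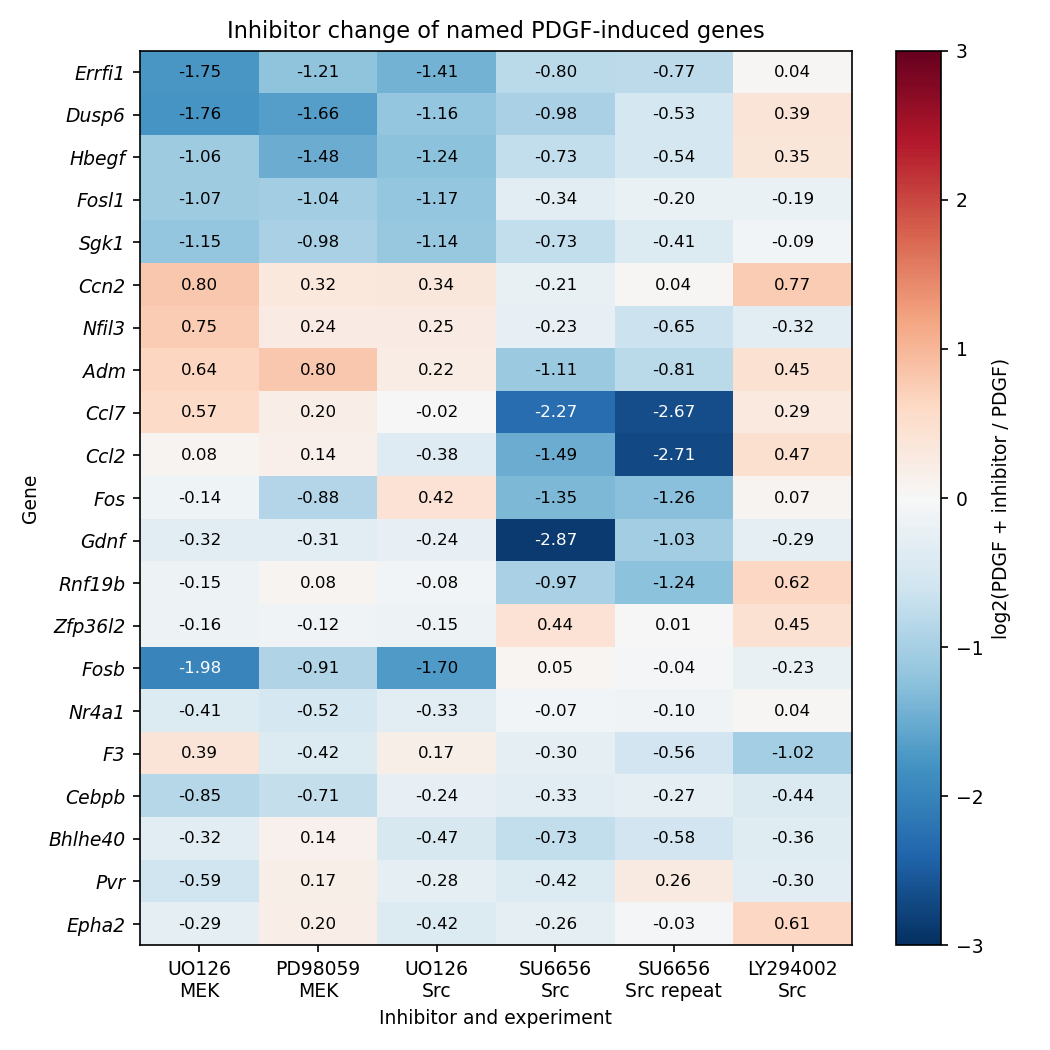
Log2 of PDGF with inhibitor over PDGF alone, 1 array each and so without error, for the genes named by inhibitor (vertical) in each inhibitor and experiment (horizontal), with values printed and coloured from blue (lower) to red (higher). Fosb is lowest with UO126 in both experiments, Dusp6 with PD98059, Gdnf and Ccl2 with SU6656 in the Src experiment and its repeat, and F3 with LY294002.

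SU6656 was used to find which responses need Src family kinases. Ranked by the weaker of 2 contrasts under PDGF, the lowest genes included the chemokine genes Ccl7 and Ccl2, with values of −2.27 and −1.49 in the Src experiment and −2.67 and −2.71 in its repeat. Fos, an AP-1 component, had −1.35 and −1.26, Gdnf, a neurotrophic factor, −2.87 and −1.03, and Rnf19b, a ubiquitin ligase gene, −0.97 and −1.24. The signal of Ccl7 was 63.4 with vehicle, 804.4 with PDGF and 134 with PDGF and SU6656 in the Src experiment, and 79.6, 2606.6 and 410.2 in the repeat. Ranked by the smaller of the 2 values, the highest were Zfp36l2 (0.44 and 0.01), Fosb (0.05 and −0.04) and Nr4a1 (−0.07 and −0.10). Over genes chosen in the other table, the median was −0.44 over 73 genes in the Src experiment (−0.518 to −0.3, 7 at least 2-fold lower and 0 higher) and −0.22 over 117 genes in the repeat (−0.339 to −0.158, 12 at least 2-fold lower and 3 higher), both below all random lists. These medians are over different gene sets. The 73 genes had to be induced in both the MEK experiment and the repeat, the 117 in the Src experiment alone. The medians therefore do not compare the size of the effect between the Src experiment and its repeat. With genes chosen in the same table, which favours lower values, they were −0.44 in the Src experiment and −0.53 in the repeat. As a change of the induction the median in the Src experiment became −0.19.

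Over both PDGF states of the Src experiment, SU6656 lowered 17 probe sets of 9 named genes and raised 0, with 1270 probe sets at an unadjusted p under 0.05 in limma. The 5 largest falls were in enzymes of cholesterol synthesis: Hmgcs1 fell by 1.87 (SE 0.235, adjusted p = 0.0192), Idi1 by 1.45 (SE 0.165, adjusted p = 0.0127), Fdft1 by 1.42 (SE 0.127, adjusted p = 0.00302), Cyp51 by 1.35 (SE 0.14, adjusted p = 0.00701) and Msmo1 by 1.35 (SE 0.104, adjusted p = 0.00204). At their brightest probe sets Hmgcs1 had −1.57, Idi1 −1.14 and Cyp51 −1.03, each also past the threshold. The other named genes, Aacs (−1.22), Stard4 (−1.11), Sc5d (−1.03) and Sqle (−0.94), were chosen after their values were seen. In the list of SREBP sterol genes, 7 of 16 fell (13 adjusted over the list alone) with a median of −0.69 and camera's adjusted p = 5.59e-35, or adjusted p = 0.0509 with an estimated correlation. The list's median was −0.58 for SU6656 over vehicle, −0.80 for PDGF with SU6656 over PDGF, and −0.24 in the repeat, where 11 of 14 members were lower and 0.02% of random lists were as low. The 17 calls became 0 without the vehicle array, 2 without the PDGF array, 7 without the SU6656 array, 11 without the filter and 0 without the variance trend.

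Camera also passed several lists with SU6656 in which limma called 0 members. Immediate early transcription factors had a median of −0.28 (adjusted p = 0.000494; 1 down adjusted over the list alone), MAPK feedback regulators −0.27 (adjusted p = 0.00273; 0 adjusted over the list alone), matrix and protease genes −0.36 (adjusted p = 0.000153; 3 down adjusted over the list alone), and heat shock and unfolded protein response genes −0.16 (adjusted p = 0.000554; 1 down adjusted over the list alone). Each of these had an adjusted p = 0.267 with an estimated correlation. Inflammatory NF-κB targets had −0.26 (adjusted p = 0.00219, and adjusted p = 0.403 with an estimated correlation), with 2 down adjusted over the list alone.

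**Figure D3:**
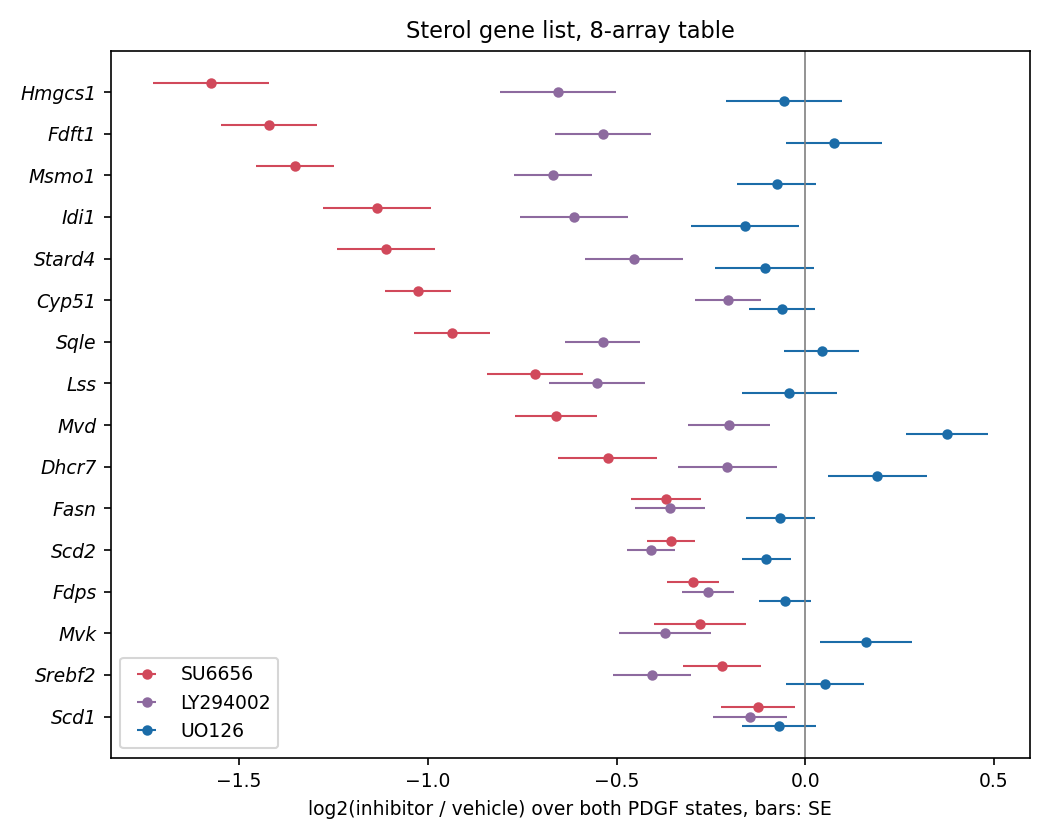
Log2 of inhibitor over vehicle for the 16 measured sterol genes in the Src experiment, fitted over both PDGF states with 2 arrays against 2, as points with standard errors (bars), at the brightest probe set of each gene. With SU6656 all 16 points are below 0, from −1.57 for Hmgcs1 to −0.13 for Scd1, and the UO126 points lie around 0.

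LY294002 was used to find which responses need PI3K. Over both PDGF states it raised 32 probe sets and lowered 49, from 21 and 39 named genes, with 14 unnamed. Herpud1, a gene of endoplasmic reticulum associated degradation, fell by 1.46 (SE 0.101, adjusted p = 8e-04) and the splicing factor gene Srsf3 by 1.51 (SE 0.179, adjusted p = 0.00955). Prkrip1 rose by 1.69 (SE 0.247) and the histone genes H2ac19 and H1f2 by 1.57 (SE 0.12) and 1.39 (SE 0.139). At the brightest probe sets Herpud1 had −1.11 and H1f2 1.23, both past the threshold. Srsf3 had −0.39 there (adjusted p = 0.138), and its 6 probe sets ran from −1.51 to 0.17. Of heat shock and unfolded protein response genes, 3 of 17 fell (9 adjusted over the list alone), with a median of −0.33 and camera's adjusted p = 1.78e-10, or adjusted p = 0.161 with an estimated correlation. They were Herpud1, the transcription factor gene Xbp1 (−0.91, SE 0.083) and the pseudokinase gene Trib3 (−0.91, SE 0.123), the last 2 chosen after their values were seen. Of SREBP sterol genes 2 of 16 fell (12 adjusted over the list alone), Msmo1 (−0.67, SE 0.104) and Scd2 (−0.41, SE 0.064, chosen after its value was seen), with a median of −0.41 (adjusted p = 3.41e-14, and adjusted p = 0.161 with an estimated correlation).

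FOXO targets had a median of 0.25 with LY294002 (camera adjusted p = 0.0306, and adjusted p = 0.335 with an estimated correlation), yet the 1 called member, Ddit4, fell by 1.12 (SE 0.164), and 1 was up and 1 down adjusted over the list alone. Txnip had 1.30 (SE 0.284, adjusted p = 0.0889). Immediate early transcription factors had a median of 0.26 (adjusted p = 0.0306, and adjusted p = 0.539 with an estimated correlation; 0 called, 3 up adjusted over the list alone), and ribosome biogenesis genes −0.20 (adjusted p = 0.0072, and adjusted p = 0.273 with an estimated correlation; 0 called, 1 down adjusted over the list alone). Under PDGF the lowest of the PDGF-induced genes were F3 (−1.02), Cebpb (−0.44), Bhlhe40 (−0.36), Nfil3 (−0.32) and Pvr (−0.30), and the highest Ccn2 (0.77), Rnf19b (0.62) and Epha2 (0.61). Over 73 PDGF-induced genes chosen in the other table the median was 0.01 (−0.076 to 0.132), at the 44th percentile of random lists, with 1 gene at least 2-fold lower and 0 higher. The median with SU6656 was lower than that with LY294002 by a median difference of −0.35 (−0.635 to −0.197), and that with UO126 by −0.19 (−0.417 to −0.12). SU6656 and UO126 differed by −0.12 (−0.263 to 0.011). All were against the same PDGF array. The 81 calls became 4 without the PDGF array, 6 without PDGF with LY294002, 8 without the vehicle array, 10 without the LY294002 array, 45 without the filter and 0 without the variance trend. Scaling to a common median gave 27 up and 27 down, and the median of induced genes became −0.08 with genes chosen in the same table. As a change of the induction the medians were −0.19 with SU6656, −0.28 with UO126 and −0.22 with LY294002, so the order of the inhibitors depended on the measure.

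The changes with an inhibitor were compared between the tables, which share no array. Over the 54 genes up in all 3 experiments, the change with UO126 in the Src experiment correlated with that in the MEK experiment (Pearson's r = 0.74, Spearman's rho = 0.775, 95% bootstrap interval of r 0.617 to 0.843). Dusp6, Errfi1 and Fosb were low in both. For SU6656 in the Src experiment and its repeat r was 0.671 (rho 0.665, interval 0.485 to 0.853), with Ccl7, Ccl2 and Gdnf low in both, and for UO126 against PD98059 it was 0.379 (rho 0.411, interval 0.12 to 0.603). The other 6 of the 9 pairs, of inhibitors of different targets, had r from −0.287 to 0.083. The mean r of same-target pairs exceeded that of the others by 0.684 (0.506 to 0.86). The same-target pairs include UO126 with UO126 and SU6656 with SU6656, the same compound in each. These correlations are across genes, which are not independent replicates, and over all genes the difference was 0.079.

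**Figure D4:**
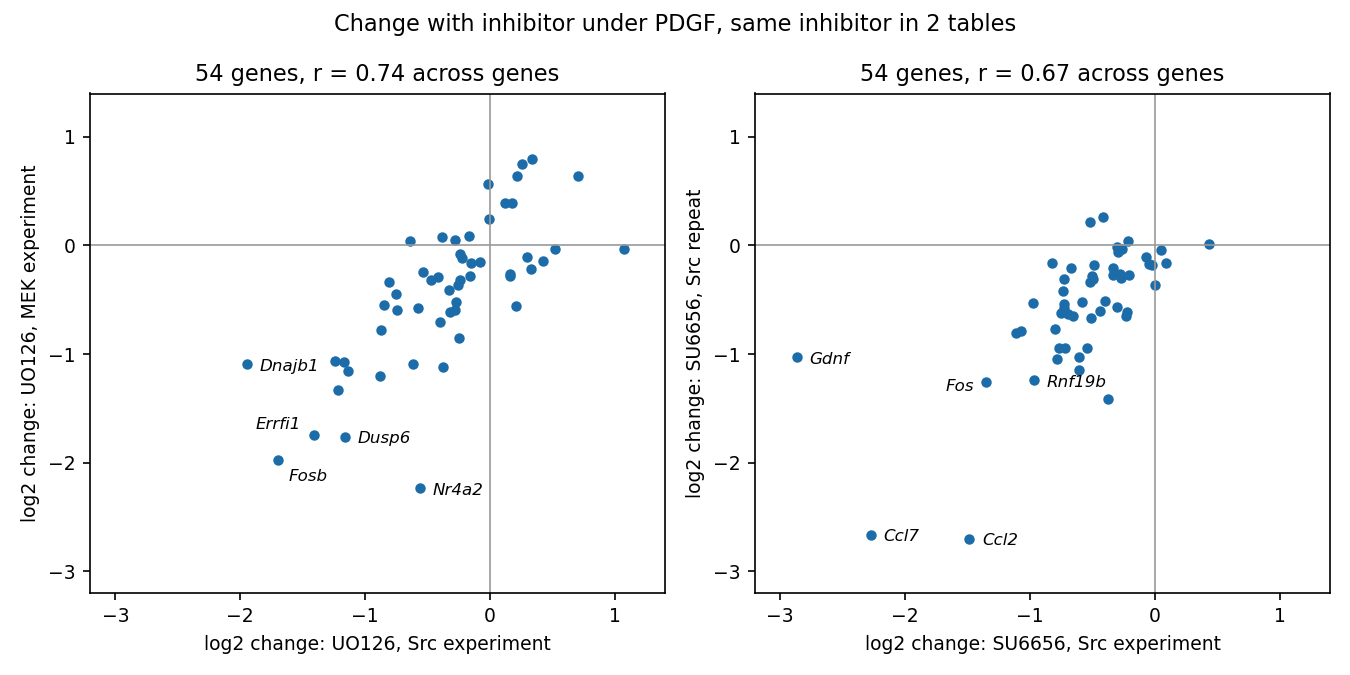
Log2 of PDGF with inhibitor over PDGF alone for 54 PDGF-induced genes, 1 point per gene, with the Src experiment on the horizontal axis and the other table on the vertical axis, for UO126 (left) and SU6656 (right). The points rise together, with r = 0.74 and 0.67 across genes, and the 5 genes with the lowest sum are named in each panel.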

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

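No test in this part was chosen before the results were seen. Zfp36l1, which encodes an AU-rich element binding protein, was the only one of the 54 genes up with PDGF in all 3 experiments whose change under PDGF went one way on every UO126 array and the other way on every SU6656 array, by at least 0.5 on the log2 scale each. With UO126 it had 0.708 in the Src experiment and 0.639 in the MEK experiment, and with SU6656 it had −0.608 in the Src experiment and −1.147 in its repeat. With PD98059, the other MEK inhibitor, it had 0.039, and with LY294002 0.31. The difference between the inhibitors was not tested, each value rests on 1 array over 1 array, and both values of the Src experiment share a PDGF array.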

How the results depend on the processing

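Leaving out whole experiments, testing lists in the inhibitor fits and leaving out or adjusting for subsets of genes were chosen after the data were seen; all other alternatives were chosen before. Among summary results, 191 values kept their call or stayed within 1.5 times the count, 15 became stronger and 27 weaker. Without the filter the calls were 11 for SU6656, 0 for UO126, 45 for LY294002, and 5 genes were down in all 3 experiments. Without the variance trend 184 (8-array) and 65 (9-array) probe sets passed for PDGF and 0 for SU6656, UO126 and LY294002. Without the pairs as a block PDGF gave 244 and 60 calls. The call for MEK inhibition under PDGF, 0 in the main setting, was 1 with values as deposited, 3 with median scaling, 1 with the offset at the 50th percentile and 6 with the lowest 50% left out. A 1.5-fold threshold gave 87 genes up and 13 down in all 3 experiments, and a 3-fold threshold 0 down. Induced genes under LY294002 had a median of 0.009 in the main setting, −0.083 with genes chosen in the same table and −0.215 as a change of the induction, which takes the inhibitor's effect without PDGF into account. The latter measure gave −0.186 for SU6656, from −0.441, and −0.285 for UO126, from −0.221. The smallest response of Txnip reversed to 0.63 without probe sets that can match several transcripts, by which another probe set represents it. With 1 array left out in turn, the ranges were 262 to 385 (PDGF, 8-array table), 98 to 111 (PDGF, 9-array table), 0 to 2 (MEK inhibition), 0 to 1 (interaction), 0 to 19 (SU6656), 0 to 8 (UO126) and 4 to 106 (LY294002); the comparison of UO126 with PD98059 stayed at 0 calls. Such fits lose a residual degree of freedom, and a lone array is assumed to vary like the others. Without 1 experiment in turn 59 to 73 genes were up and 4 to 17 down, by construction with fewer conditions to meet. For other differences the cause was not tested. Among genes named from a fit, 196 values became weaker, 17 stronger and 2611 stayed. Among lists the numbers were 11, 7 and 1018, and among genes named by inhibitor 11, 1 and 156. Values that stayed include those past the threshold in neither setting. Lists were retested only under other scalings, offsets and filters, not with an array left out or without the block or trend. For genes named by inhibitor the threshold was a 2-fold change. The median of all genes moved by less than 0.1 under every scaling. Genes near the offset have understated changes, and weak signal over background limits their calls.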

Other observations

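The tests on the sterol genes, on the correlations between inhibitors and on the overlap of lowered genes were chosen after the results were seen; the count of other splits of the arrays was chosen before. In the MEK experiment without PDGF, the aryl hydrocarbon receptor battery had a median of 0.46 with UO126 and 0.78 with PD98059 over the untreated array, at the 99.7th and 100th percentile of random lists. Cyp1a1, a cytochrome of xenobiotic metabolism outside the rule for named genes, had 1.76 and 1.84. Tiparp, a poly-ADP-ribosyl transferase gene, had 1.11 and 0.91. With PDGF the medians of the 5 genes were −0.15 and −0.01, and UO126 over vehicle in the Src experiment gave 0.07. Both of the former values share the untreated array with a Gapdh 3′ to 5′ ratio of 1.13. The labels call that control untreated and the control of the Src experiment vehicle-treated. In the MEK experiment a difference in vehicle therefore cannot be told apart from the inhibitor. LY294002 without PDGF gave immediate early transcription factors a median of 0.33, at the 100th percentile, and 0.07 with PDGF. The percentiles given here are not adjusted over the lists and single-array contrasts that were examined.

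Sterol genes had a median of −0.688 with SU6656 in the 8-array table. In the values as deposited the list median lay −0.715 from the median of all genes, against −0.075 to 0.107 for random lists. The shift was therefore present without the quantile normalisation. This distance cannot test a scale factor common to all genes, which cancels in it. The list was also picked for lying below other genes on the same arrays. A single aberrant array is argued against by the weakest of 3 contrasts that share no array, −0.242, against −0.092 to 0.122 for random lists. High vehicle arrays are argued against by UO126 alone, which gave −0.055 against the same vehicle arrays. LY294002 gave −0.408 against them, so this explanation is not excluded. A hypothesis left open is that inhibition by SU6656, of Src family kinases or of other targets, may lower SREBP-driven transcription; no second Src inhibitor was measured, and the call was lost with an estimated correlation (adjusted p = 0.0509).

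The correlations of inhibitor changes were higher for inhibitors of one target, by 0.684. UO126 with UO126 (r = 0.74) and SU6656 with SU6656 (0.671) are pairs of the same compound. UO126 with PD98059, different compounds with one target, had 0.379. The difference of 0.684 therefore cannot part a shared target from other effects of a compound. A few genes as the cause are argued against, since the difference was 0.595 (0.403 to 0.772) without 10 genes that were farthest from the median for any inhibitor, with 44 left. Shared dependence on induction size or signal level is argued against, since the difference was 0.69 (0.511 to 0.865) after both were regressed out. As a hypothesis, the genes may differ in their dependence on MEK and on Src family kinases; with 1 array per condition, other differences between inhibitors stay open.

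Of the 54 genes, 10 were at least 1.5-fold lower in all 3 MEK inhibitor contrasts and 16 in both SU6656 contrasts. Errfi1 was the 1 gene in both sets, against 2.96 expected of independent sets. Independence was not excluded (one-sided Fisher's exact p = 0.129), so the small overlap may be chance, and genes are not independent replicates. The Src experiment's UO126 and SU6656 values share a PDGF array, and the genes were chosen on the PDGF arrays they are measured against, which favours lower values.

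For the PDGF effect, the real split of the 8 arrays gave 525 calls in the 8-array table and 147 in the 9-array table. Of the 8 splits in which both arrays of every pair are parted, 1 in each table, the real one, gave as many, and the highest of the others gave 0. These splits are too few for a share under 0.05. The 24 splits that part 2 of the pairs also gave 0, and the 3 that part none could not be fitted. Every split other than the real one left PDGF differences in its residual, which favours 0 calls. These counts of 0 therefore do not show how many calls would arise without a PDGF effect.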
